A study of Nematostella vectensis with 76 samples.

How the data were processed

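Whole-body RNA of adult Nematostella vectensis, the starlet sea anemone, was measured in 76 libraries. Per the labels, the series held 19 conditions with 4 replicates each, and animals spent 7 days in their condition. Total RNA was extracted from preserved whole animals and the libraries followed the method of Meyer and colleagues, per the labels' protocols. Bowtie2 was named in the submitters' processing notes without a version, and the genome of Putnam and colleagues was named in the sample descriptions. The program that turned alignments into counts per gene is not given in the sources used here.

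The authors deposited 1 table of whole-number counts for 23986 gene identifiers, and all of its 76 columns matched a sample by title. Every analysis started from those deposited counts. The total per library ran from 115466 to 942638 counts with a median of 522108, so genes of low expression were read with wide errors in the shallowest libraries. The gene identifiers carry NVE numbers. The gene table used here for names covers assembly jaNemVect1.1, and 0 of the identifiers matched it. Gene names, products and coordinates are therefore not printed, and the tests of gene lists written down before the data were examined could not be run, because they searched product names. By the rule fixed for that case, the text names identifiers by the smallest p, 1 higher and 1 lower per comparison, and says so where one was chosen otherwise.

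Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr on the 19 groups, which left 9164 genes, and libraries were scaled with TMM factors. A single negative binomial model with 1 coefficient per group and 57 residual degrees of freedom was fitted with estimateDisp and glmQLFit, and each comparison was a contrast tested with glmQLFTest. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are called below. The typical biological coefficient of variation was 22.1%. Standard errors are the fitted log2 fold change divided by the square root of its F statistic. CPM values are counts scaled by the TMM-adjusted library size, and principal components used log2 CPM with a prior count of 3.

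Apart from those named as chosen after the data were seen, the comparisons, tests and alternatives were fixed before the data were examined. They comprised 27 comparisons: antibiotic controls against each other and against untreated animals, each of 8 exposures against the control with or without antibiotics, LPS doses, live bacteria against supernatant, antibiotics over all exposures, their interaction with exposure, and bacterial species. The labels do not say which antibiotic control belongs with the exposures given with antibiotics, nor when antibiotics were given in those groups. The group with antibiotics removed was used, and the group kept on antibiotics was the alternative. A further 18 comparisons were added after the data were seen: single exposures with against without antibiotics, live against supernatant within 1 bacterium, and the interaction for each exposure. Alternatives were DESeq2 1.42.0, RLE size factors in edgeR, no filter beyond 1 count in any library, the replicate number as a block, a fit of only the groups compared, and each library left out. The filter was run again wherever libraries were left out of a fit. Leaving out the 16 libraries numbered 99 to 114 was chosen after seeing the data, as were the tests of Bacillus exposure and of library composition.

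Replicates within a group were compared by a chi-square over genes with at least 20 summed counts. The lowest value was 1.51 per degree of freedom, so no pair of libraries of the same group agreed within sampling noise and all 76 were kept. Libraries of different groups were not compared in this way. The labels do not say whether replicates were separate animals or pools, so p-values measure the spread between these libraries. The procedure was tested on simulated counts for 9164 genes. For live Vibrio against no treatment, edgeR recovered 31% of genes changed 2-fold and 84% of genes changed 4-fold, and called 5 unchanged genes. For Bacillus supernatant with against without antibiotics, where the libraries were shallow, it recovered 11% and 49%.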

Results

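Adult sea anemones were profiled after 7 days without treatment, with antibiotics, or in 1 of 8 exposures, each given with and without antibiotics. The labels do not say when the antibiotics were given relative to the exposure. The exposures were live cells and cell-free supernatant of 3 bacteria (Vibrio alginolyticus, Bacillus velezensis and Pseudoalteromonas spiralis, called by genus from here on) and lipopolysaccharide (LPS), a component of the outer membrane of Gram-negative bacteria, at 5 ng/mL and 5 µg/mL. Of the unexposed groups, 1 was untreated, 1 was kept on antibiotics and 1 had the antibiotics removed 3 days before extraction. Each of the 19 groups had 4 libraries, with totals from 115466 to 942638 counts. Untreated libraries averaged 452617 ± 104044 counts (SD, n = 4).

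The labels number the samples from 67 to 142, and 16 libraries numbered 99 to 114 stood apart. They were all the libraries of 4 groups: Bacillus supernatant with and without antibiotics, live Bacillus with antibiotics, and live Pseudoalteromonas without antibiotics. Their totals lay between 115466 and 347127 counts, against 298546 to 942638 in the other 60 libraries. On the first principal component, which held 29.6% of the variance, their scores lay from 38.98 to 82.2 and those of the others from -35.4 to 3.64. The identifier NVE12279 took 5.07% to 10.7% of their counts and 0.647% to 3.45% elsewhere. Within each of these 4 groups no library lay outside that stretch of numbers, so in comparisons with other groups the exposure and the stretch cannot be told apart. Inside it, the pairs of groups that differed in a single factor were Bacillus supernatant with against without antibiotics, and live Bacillus against its supernatant with antibiotics. Each of the 19 groups held consecutive numbers, with the unexposed groups at 67 to 78 and the exposed groups at 79 to 142. No comparison between groups therefore separates the condition from the order of the sample numbers, whose meaning the labels do not give.

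**Figure D1:**
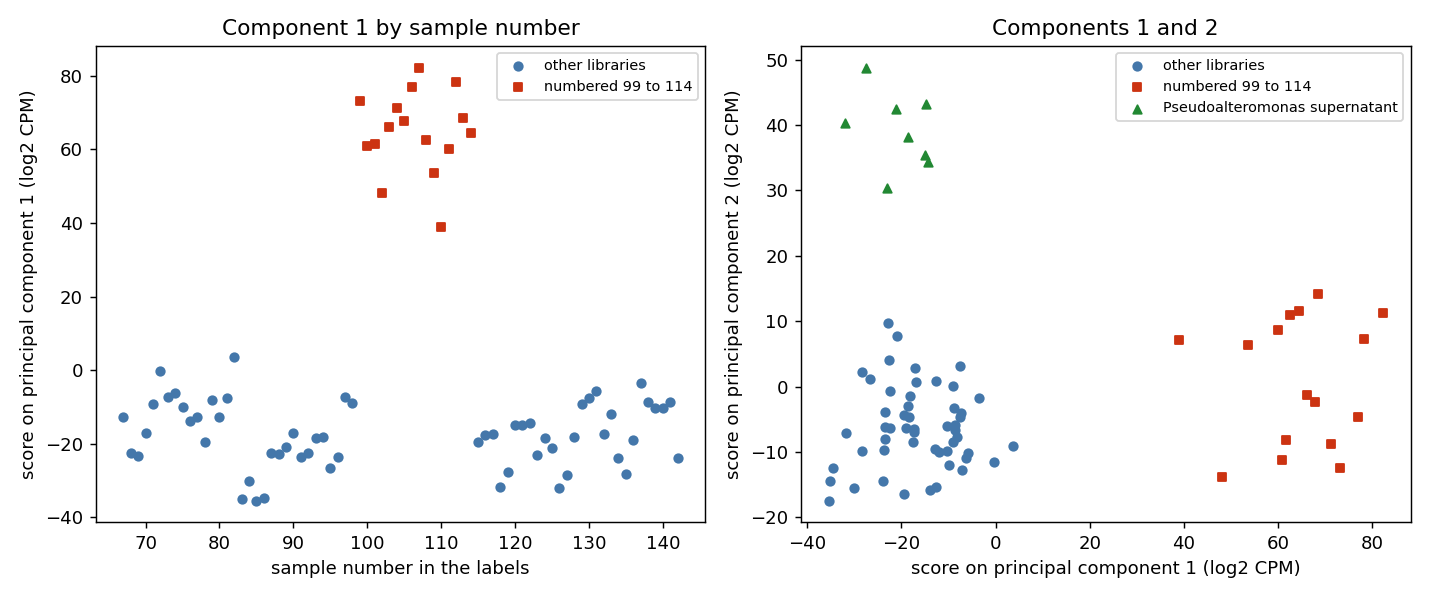
Left, the score of each of the 76 libraries on principal component 1 of log2 CPM against the sample number in the labels. Right, components 1 and 2; the 16 libraries numbered 99 to 114 score 38.98 or more on component 1 and the others 3.64 or less, and the Pseudoalteromonas supernatant libraries score 30.3 or more on component 2.

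To ask what antibiotics alone did, unexposed groups were compared. In animals kept on antibiotics, 226 genes were higher and 266 lower than in untreated animals. NVE6951 was 12.1-fold higher, at 52.5 ± 9.91 CPM against 3.60 ± 3.66 CPM (SD, n = 4 each; log2 3.59, SE 0.44, edgeR adjusted p = 1.01e-07). NVE16219 was lower, at 8.71 ± 3.14 against 112 ± 33.3 CPM (log2 -3.62, SE 0.46, edgeR adjusted p = 1.23e-07). With RLE size factors the split was 304 higher and 204 lower, and with DESeq2 354 and 233, so the balance of directions rested on the method. After removal, 10 genes were higher and 27 lower than in untreated animals. NVE10051 was lower, at 2467 ± 669 against 8702 ± 1617 CPM (log2 -1.82, SE 0.31, edgeR adjusted p = 0.000607). Of the called genes, 21 were shared by both antibiotic groups; 6 were higher and 14 lower in both, where independent lists of these sizes would share 0.247 and 0.784. Both comparisons used the untreated libraries. Across genes their fold changes correlated at 0.55, against 0.52 in simulated groups without any change, and the covariance was 0.170 against 0.0945. In the simulated groups 0 genes were called higher and 0 lower in both. As these groups held no change, few genes could be called in either comparison. That result therefore cannot tell what overlap a shared control gives between lists of the observed sizes. With the untreated libraries split 2 and 2, the correlation averaged 0.23 over 6 arrangements, and the genes shared averaged 0.5 higher (0 to 2) and 4.17 lower (2 to 6). Removed and maintained animals differed directly, with 90 genes higher and 114 lower after removal. NVE825 was 4.81-fold lower after removal, at 399 ± 48.0 against 1919 ± 166 CPM (log2 -2.27, SE 0.29, edgeR adjusted p = 1.84e-07). In each named case all 4 libraries lay beyond the mean of the other group. The maintained comparison called 319, 280 and 253 genes without untreated replicates 2, 3 and 4 and 321 without maintained replicate 3. The removed comparison called 18, 18 and 13 without those untreated libraries and 19, 16 and 16 without removed replicates 2, 3 and 4, and removed against maintained called 113 and 110 without removed replicates 2 and 4 and 128 without maintained replicate 3. The removed comparison called 83 genes with no filter and 118 with only the 2 groups fitted, and DESeq2 called 98 for it, 52 higher and 46 lower.

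Without antibiotics, live Vibrio changed no gene past the threshold (edgeR, 0 genes; 330 genes at an unadjusted p under 0.05; DESeq2, 0 genes; no filter, 3 genes). Its supernatant gave 232 genes higher and 117 lower, or 205, 222 and 190 in all without untreated replicates 2, 3 and 4 and 186 and 219 without supernatant replicates 2 and 3. NVE6003 rose 25.9-fold with the Vibrio supernatant, from 8.52 ± 4.54 to 224 ± 110 CPM (SD, n = 4 each; log2 4.69, SE 0.43, edgeR adjusted p = 4.76e-13), and NVE24322 fell from 59.1 ± 10.2 to 11.7 ± 2.72 CPM (log2 -2.30, SE 0.33, edgeR adjusted p = 2.06e-06). Supernatant of Pseudoalteromonas gave 691 genes higher and 422 lower. NVE5443 rose 58.6-fold, from 27.99 ± 13.3 to 1682 ± 180 CPM (log2 5.87, SE 0.30, edgeR adjusted p = 7.15e-27), and NVE6091 fell from 484 ± 41.8 to 167 ± 36.9 CPM (edgeR adjusted p = 1.58e-08). Live Bacillus gave 48 genes higher and 11 lower, among them NVE11386 at 180 ± 27.8 against 69.1 ± 10.9 CPM (log2 1.40, SE 0.22, edgeR adjusted p = 0.00019). That count was not steady. It was 12, 6 and 9 without untreated replicates 2, 3 and 4, and 36, 12 and 16 without live Bacillus replicates 1, 2 and 3. It was 167 with DESeq2, 100 with no filter and 15 when only the 2 groups compared were fitted.

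The remaining live and supernatant groups without antibiotics were among the libraries numbered 99 to 114. Live Pseudoalteromonas gave 850 genes higher and 1385 lower, and Bacillus supernatant 1096 higher and 1488 lower. NVE12279 was 9.45-fold higher with live Pseudoalteromonas, at 117085 ± 24689 against 12391 ± 2905 CPM (SD, n = 4 each), and NVE15860 was lower in both groups, at 47.1 ± 18.1 and 33.3 ± 20.9 against 306 ± 38.3 CPM. These differences cannot be told apart from the stretch of sample numbers. Without live Pseudoalteromonas replicate 3 its count was 1423. With only the 2 groups fitted and the filter run again, the balance of directions turned, to 714 higher and 602 lower of 2954 genes tested for live Pseudoalteromonas and 928 and 685 of 3468 for Bacillus supernatant; with no filter it was 466 and 1665, and 699 and 1594.

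**Figure D2:**
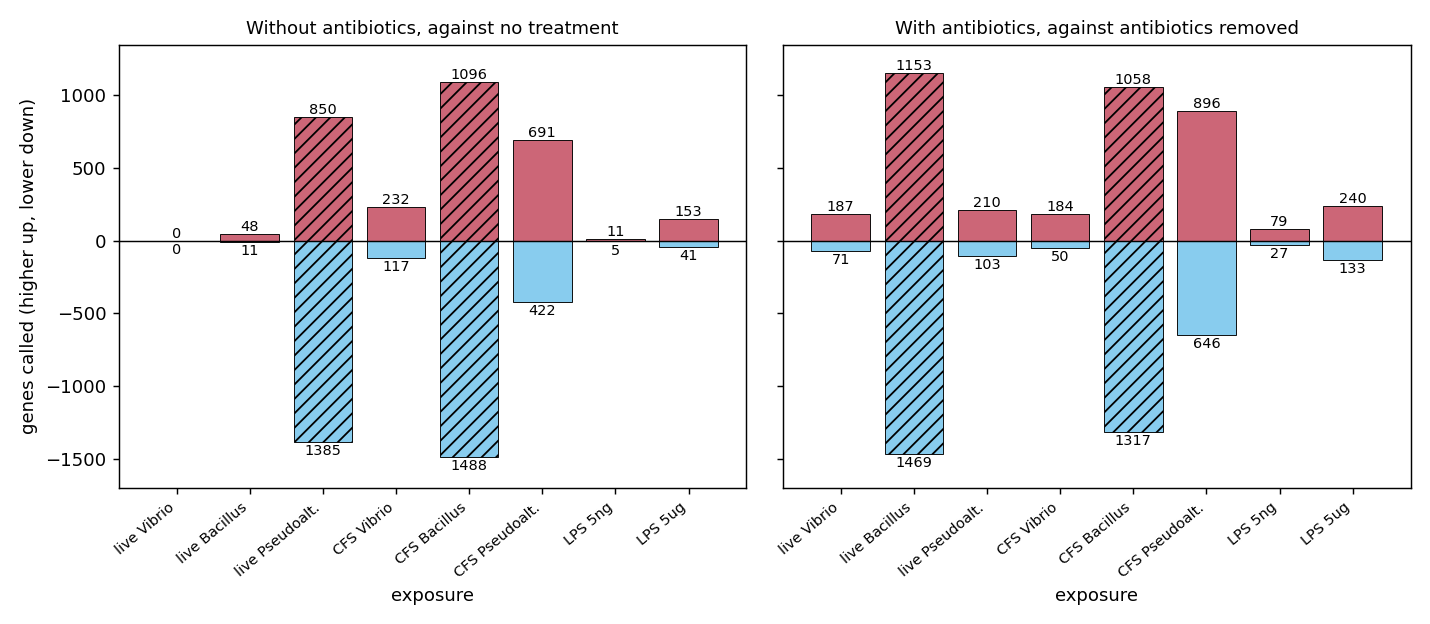
Genes called higher (upward bars) and lower (downward bars) by edgeR for each exposure against its control, without antibiotics on the left and with antibiotics on the right, 4 libraries per group (CFS, cell-free supernatant; Pseudoalt., Pseudoalteromonas). Hatched bars use libraries numbered 99 to 114; outside them the Pseudoalteromonas supernatant bars are the tallest, with 691 and 896 genes higher.

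Each exposure with antibiotics was compared with the group whose antibiotics had been removed. Live Vibrio gave 187 genes higher and 71 lower, and NVE24289 rose from 166 ± 23.5 to 439 ± 37.7 CPM (SD, n = 4 each; log2 1.40, SE 0.24, edgeR adjusted p = 0.000725). Vibrio supernatant gave 184 higher and 50 lower. NVE7499 rose 15.4-fold, from 12.2 ± 3.04 to 193 ± 49.4 CPM, and NVE24322, the identifier that fell with this supernatant without antibiotics, was lower here also, at 7.89 ± 3.77 against 52.8 ± 5.54 CPM (log2 -2.72, SE 0.38, edgeR adjusted p = 3.27e-07). Live Pseudoalteromonas gave 210 higher and 103 lower, with NVE8784 at 95.6 ± 21.9 against 15.1 ± 6.06 CPM (edgeR adjusted p = 4.32e-06). Its supernatant gave 896 higher and 646 lower, with NVE5443 rising 62.9-fold from 23.7 ± 8.34 to 1506 ± 151 CPM (log2 5.98, SE 0.30, edgeR adjusted p = 7.54e-27). In the stretch of numbers 99 to 114, live Bacillus gave 1153 higher and 1469 lower and Bacillus supernatant 1058 higher and 1317 lower. With only the 2 groups fitted these were 925 and 868, and 783 and 709. With no filter they were 705 and 1738, and 637 and 1607. Against the group kept on antibiotics, the counts were 614 for live Vibrio, 712 for live Pseudoalteromonas and 439 for Vibrio supernatant. Without antibiotics-removed replicates 1, 2 and 3 in turn, live Vibrio gave 102, 137 and 142 genes and live Pseudoalteromonas 111, 149 and 182. Live Vibrio gave 131 without its own replicate 3 or 4, live Pseudoalteromonas 144 without its replicate 1, and Vibrio supernatant 155 without antibiotics-removed replicate 4.

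Fold changes of an exposure with and without antibiotics used no common library, and were set side by side across genes, which are not independent replicates. For Pseudoalteromonas supernatant they correlated at 0.73 (Spearman 0.63). Called higher both with and without antibiotics were 510 genes and called lower in both were 220, where independent lists would share 67.6 and 29.7, and 0 genes were called in opposite directions. For Vibrio supernatant the correlation was 0.35, with 77 genes higher and 18 lower in both against 4.66 and 0.638 for independent lists. The correlations were 0.34 and 0.30 for LPS at 5 ng/mL and 5 µg/mL and -0.01 for live Vibrio. For the exposures with libraries numbered 99 to 114 they were 0.59 for Bacillus supernatant, with both groups in that stretch, and -0.19 for live Bacillus and 0.02 for live Pseudoalteromonas, each with 1 group in it. Called in opposite directions were 12, 37 and 42 genes in that order, and called in the same direction 607 higher and 714 lower, 1 and 1, and 8 and 30. Over all 8 exposures, matched exposures averaged 0.26 and mismatched ones 0.14 (one-sided exact permutation test over 40320 pairings, p = 0.0734). Over the 5 exposures outside the stretch of sample numbers, a set chosen after the data were seen, the averages were 0.34 and 0.20 (120 pairings, one-sided exact p = 0.05).

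**Figure D3:**
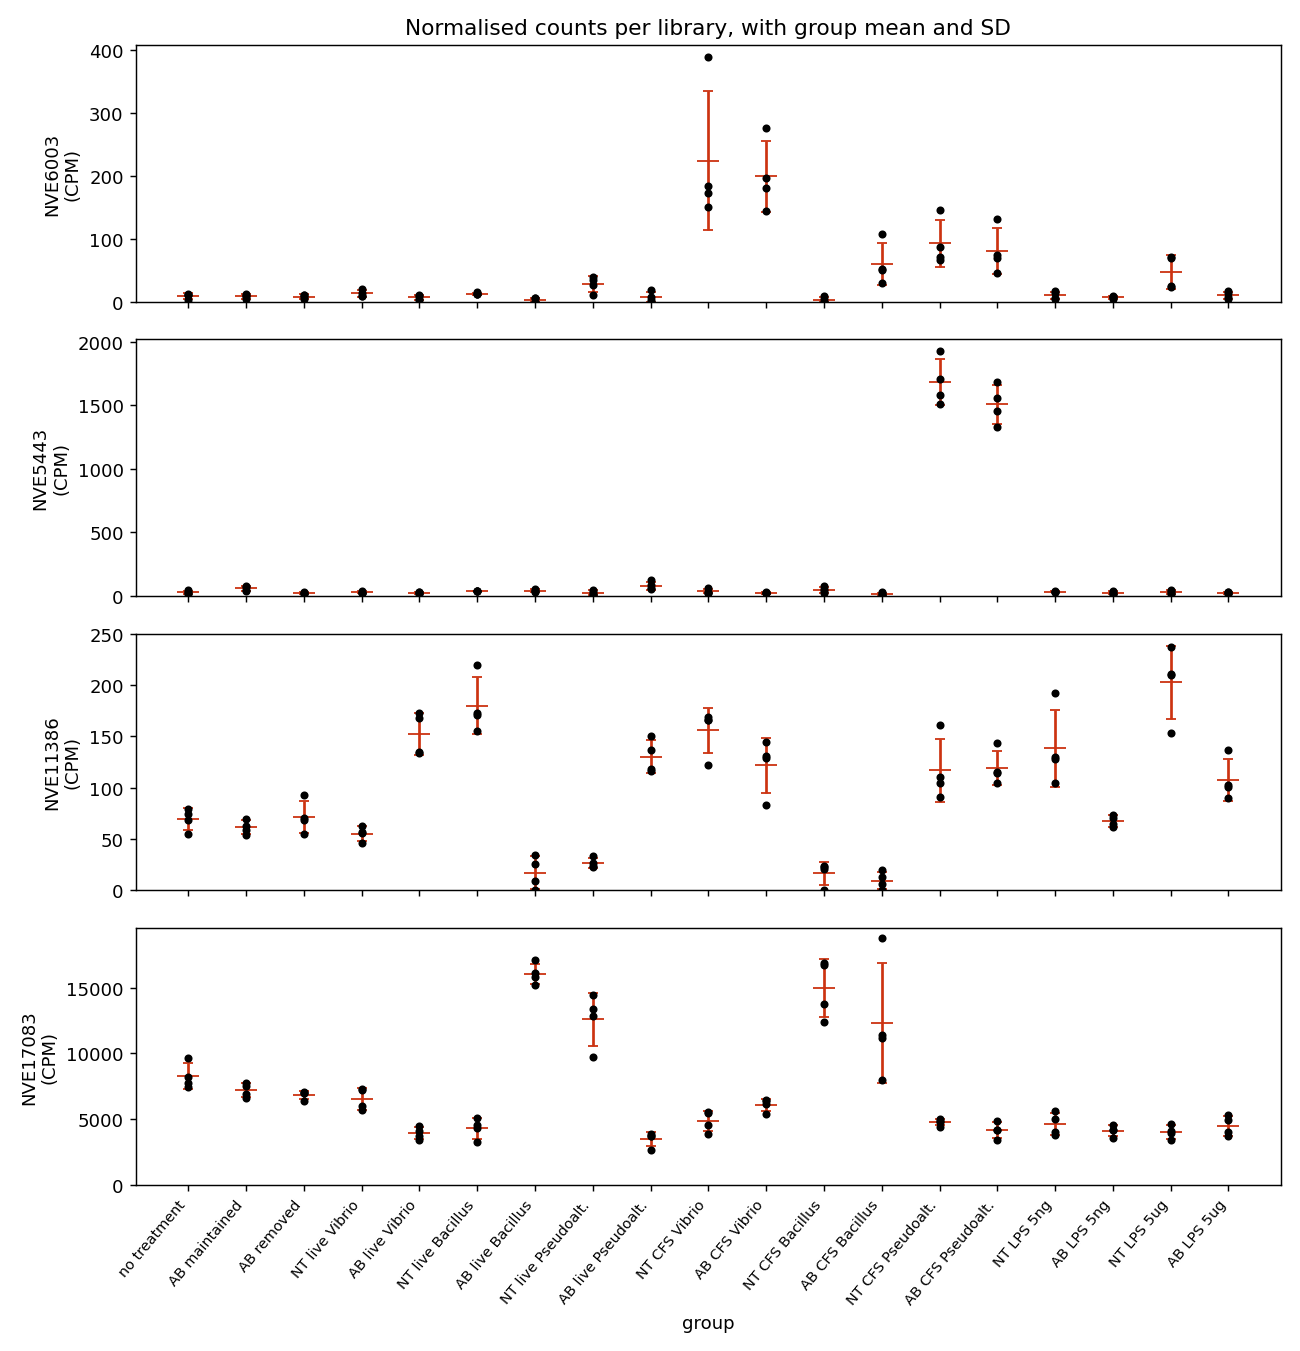
CPM of 4 identifiers (vertical axes from 0) in each library of the 19 groups, with the group mean and SD in red and n = 4 per group (NT, without antibiotics; AB, with antibiotics; CFS, cell-free supernatant). NVE5443 reaches 1682 and 1506 CPM on average in the Pseudoalteromonas supernatant groups, NVE6003 averages 224 CPM with Vibrio supernatant without antibiotics, and NVE17083 averages 8260.4 CPM in untreated libraries.

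LPS without antibiotics gave 11 genes higher and 5 lower at 5 ng/mL and 153 higher and 41 lower at 5 µg/mL. NVE17083 fell at both doses, to 4584 ± 841 and 4009 ± 520 CPM from 8260.4 ± 970 CPM (SD, n = 4 each; log2 -0.85 and -1.04, SE 0.16 each, edgeR adjusted p = 0.00311 and 1.06e-05). NVE11386, which rose with live Bacillus, was 2.95-fold higher at the upper dose. Neither identifier was particular to LPS. NVE17083 was also lower with live Bacillus without antibiotics, at 4266 ± 772 CPM. Inside the stretch of sample numbers, with live Bacillus and antibiotics, both moved the other way against the antibiotics-removed group. The log2 fold changes there were 1.23 for NVE17083 and -1.91 for NVE11386. Whether these identifiers followed library composition rather than the exposure was not tested. With antibiotics the doses gave 79 higher and 27 lower, and 240 higher and 133 lower. NVE9353 rose from 70.8 ± 3.67 to 253 ± 54.1 CPM at 5 µg/mL (edgeR adjusted p = 2.23e-06). The doses, 1000-fold apart, differed directly by 1 gene without antibiotics, NVE4826, at 55.0 ± 16.5 against 15.8 ± 11.2 CPM (edgeR adjusted p = 0.0397). That call was lost with only the 2 groups fitted, and without 5 ng/mL replicate 1, 2 or 4 or 5 µg/mL replicate 2 or 4, and 4 of the 35 splits of these 8 libraries gave as many genes. The doses differed by 2 genes with DESeq2, 14 with no filter and 0 to 8 with 1 library left out. They differed by 0 genes with antibiotics (edgeR; 416 at an unadjusted p under 0.05; DESeq2, 0 genes; no filter, 2 genes). At the lower dose without antibiotics, 0 genes were called when only the 2 groups were fitted, 78 with DESeq2, 25 with no filter, 1 and 5 without LPS replicates 1 and 4, and 6, 8, 2 and 9 without untreated replicates 1 to 4. At the upper dose 76 genes were called without LPS replicate 1 and 94 and 103 without untreated replicates 3 and 4, and the count was 1.58 times lower without untreated replicate 2. With antibiotics, the doses gave 507 and 962 genes against the group kept on antibiotics. The lower dose gave 165 with no filter, 61, 53 and 163 without LPS replicates 1, 3 and 4 and 57, 67 and 61 without antibiotics-removed replicates 1, 2 and 3. The upper dose gave 163 without LPS replicate 2 and 171, 237 and 239 without those antibiotics-removed libraries.

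Live cells were compared with supernatant over the 3 bacteria. With antibiotics, 228 genes were higher and 471 lower with live cells. NVE6003 was lower with live cells, at 5.44 ± 5.28 against 113 ± 75.1 CPM (SD, n = 12 each; log2 -4.14, SE 0.33, edgeR adjusted p = 1.07e-15). Without antibiotics, 39 genes were higher and 78 lower, but there 1 live group and a supernatant group of another bacterium lay among the libraries numbered 99 to 114. Without replicate 2, 3 or 4 of every group, the counts were 365, 463 and 461 with antibiotics, and without replicate 2 76 without antibiotics. Leaving out the libraries numbered 99 to 114, a choice made after the data were seen, also left out bacteria. The count was then 1255 with antibiotics, over Vibrio and Pseudoalteromonas, and 464 without antibiotics, for Vibrio alone. These are not the same tests as those over the 3 bacteria. Within single bacteria, comparisons added after the data were seen gave 112 higher and 209 lower for Vibrio without antibiotics, 225 and 227 for Vibrio with antibiotics, and 213 and 579 for Pseudoalteromonas with antibiotics. The first of these fell to 127 genes without live Vibrio replicate 4 and 212 without supernatant replicate 1, and was 500 with DESeq2. NVE6003 was lower with live Vibrio than with its supernatant without and with antibiotics, by log2 -4.18 ± 0.40 and -4.89 ± 0.43 (SE). For Bacillus with antibiotics, inside the stretch of sample numbers, 22 genes were higher and 90 lower with live cells. NVE2343 was lower there, at 76.8 ± 29.3 against 907 ± 318 CPM (SD, n = 4 each; edgeR adjusted p = 4.95e-14). The count was 69 without supernatant replicate 4, 73 without supernatant replicate 2 or live replicate 2, and 55 with only the 2 groups fitted, 20 higher and 35 lower.

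The groups of the 3 bacteria differed from one another in 2626 genes as live cells and in 5493 genes as supernatant (edgeR F tests with and without antibiotics together). Both Bacillus supernatant groups lay among the libraries numbered 99 to 114. So did live Bacillus with antibiotics and live Pseudoalteromonas without. These counts therefore cannot tell the bacterium from the stretch of sample numbers. Without the libraries numbered 99 to 114, a choice made after the data were seen, the groups left gave 372 genes for live cells and 1855 for supernatant. The live count set Bacillus against Vibrio only without antibiotics, and Pseudoalteromonas against Vibrio only with antibiotics. It is therefore not the same test as the one that gave 2626. The supernatant count compared Pseudoalteromonas with Vibrio, with 1004 genes higher and 851 lower in Pseudoalteromonas. Without replicate 3 of every group, 1217 genes were called for live cells.

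Animals with antibiotics were set against those without over all 8 exposures. There were 502 genes higher and 587 lower with antibiotics, but 590 and 536 with RLE size factors and 641 and 573 with DESeq2, so the balance of directions rested on the method. Leaving replicate 3 or replicate 4 out of every group gave 608 or 619 genes. NVE24607 was 5.31-fold lower, at 159 ± 108 against 742 ± 348 CPM (SD over 32 libraries each; log2 -2.41, SE 0.15, edgeR adjusted p = 7.88e-22), and NVE2965 was higher, at 962 ± 380 against 583 ± 309 CPM (log2 0.85, SE 0.08). Each side had 2 groups in the stretch of sample numbers, and the 5 exposures outside it gave 1183 genes. By single exposure, live Vibrio with antibiotics had 617 genes higher and 511 lower than without, or 850 and 382 with RLE size factors, which moved its fold changes by 0.10 on the log2 scale. Without live Vibrio replicate 4 of the animals without antibiotics, 574 genes were called. Vibrio supernatant differed in 4 and 8 genes, Pseudoalteromonas supernatant in 11 and 8, LPS at 5 ng/mL in 1 and 11, and LPS at 5 µg/mL in 57 and 114. These counts were not steady. For LPS at 5 µg/mL they were 77 (4 higher, 73 lower) without replicate 2 with antibiotics, 106 without replicate 3 with antibiotics and 78 without replicate 4 without antibiotics, and 274 with no filter. For LPS at 5 ng/mL they were 3, 7, 5 and 7 without each of replicates 1 to 4 with antibiotics and 7 without replicate 2 without antibiotics, and 2 with only the 2 groups fitted, 29 with DESeq2 and 54 with no filter. For Vibrio supernatant they were 6 without replicate 1 with antibiotics and 7 without replicate 2 without antibiotics, 21 with only the 2 groups fitted and 75 with no filter. For Pseudoalteromonas supernatant they were 11 and 12 without replicates 1 and 2 with antibiotics, 11, 11 and 9 without replicates 1, 2 and 4 without antibiotics, 10 with only the 2 groups fitted, 49 with DESeq2, 56 with no filter and 35 without the libraries numbered 99 to 114. Bacillus supernatant, inside the stretch, differed in 83 and 44, with NVE2343 10.8-fold higher with antibiotics at 907 ± 318 against 80.1 ± 38.6 CPM. That count was 57 without replicate 4 with antibiotics, 84 without replicate 3 or replicate 4 without antibiotics, and 27 with only the 2 groups fitted, where 1679 genes were tested.

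Whether the response to an exposure differed with and without antibiotics was tested as an interaction. Over all exposures 3220 genes were called, 2113 without replicate 3 of every group, and 238 over the 5 exposures outside the stretch. Single interactions called 10 genes for live Vibrio, 1 for Vibrio supernatant, 2 for Pseudoalteromonas supernatant, 3 for LPS at 5 µg/mL and 0 for LPS at 5 ng/mL (edgeR; 369 genes at an unadjusted p under 0.05; DESeq2, 0 genes). The counts moved with the method. With DESeq2, no filter and only the groups compared in turn, they were 81, 91 and 73 for live Vibrio, 2, 21 and 5 for Vibrio supernatant, 9, 13 and 3 for Pseudoalteromonas supernatant, 25, 70 and 9 for LPS at 5 µg/mL, and 0, 1 and 0 for LPS at 5 ng/mL. With 1 library left out they were 0 to 15 for live Vibrio, 0 to 2 for Vibrio supernatant, 1 to 5 for Pseudoalteromonas supernatant, 0 to 8 for LPS at 5 µg/mL and 0 to 2 for LPS at 5 ng/mL. The live Vibrio interaction was 0 genes without any 1 of untreated replicates 2, 3 or 4, antibiotics-removed replicate 1, or live Vibrio replicate 4 with or without antibiotics. For LPS at 5 µg/mL it was 0 without antibiotics-removed replicate 1, and 8 without untreated replicate 1 or LPS replicate 4 with antibiotics.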

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

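The test of Bacillus exposure was chosen after the result was seen; the thinning test and the splits of samples were fixed before.

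Across 89 groups of 4 libraries, 4 had a library far from the others, where chance gives about 1 in 20. NVE12279 stood at 16703 CPM in untreated replicate 2, against 10441 to 11465 in the others. NVE6003 stood at 388 CPM in Vibrio supernatant without antibiotics replicate 2, against 150.0 to 184 CPM. NVE17083 was at 2625 CPM in live Pseudoalteromonas with antibiotics replicate 4, against 3676 to 3840, and at 6357 CPM in antibiotics-removed replicate 4, against 6930 to 7023.

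Responses that differed with and without antibiotics by the interaction test were 3220 genes over all exposures. Singly they were 2152 for live Bacillus, 1526 for live Pseudoalteromonas, 36 for Bacillus supernatant (63 with DESeq2, and 25 to 63 with 1 library left out), 10 for live Vibrio, 3 for LPS at 5 µg/mL, 2 for Pseudoalteromonas supernatant and 1 for Vibrio supernatant. Among named identifiers, 8 of 26 responses differed, each for a live bacterium with 1 of its 2 groups inside the libraries numbered 99 to 114. For live Bacillus, with minus without antibiotics, the log2 differences were -3.31 for NVE11386, 2.18 for NVE17083, 2.11 for NVE23474 and -2.68 for NVE19791. For live Pseudoalteromonas they were -2.75 for NVE12279, 2.69 for NVE15860, 5.47 for NVE8784 and -1.59 for NVE17083.

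The 16 libraries numbered 99 to 114 stood apart from the other 60. Depth alone is argued against, since after every library was thinned to 115466 counts the lowest of the 16 still lay 21.4 above the highest of the others on the first component. Exposure to live Bacillus as such is argued against as well. Fold changes of live Bacillus with antibiotics, inside the stretch, and without, outside it, correlated across genes at -0.19. Those of Bacillus supernatant without antibiotics and live Bacillus with antibiotics, which share no library, correlated at 0.63. Both of these groups lie inside the stretch, so that value cannot tell Bacillus from the stretch. Whether Bacillus supernatant as such sets its libraries apart was not tested. A technical run and an effect of these 4 exposures against their controls both stay open and cannot be told apart, as each group lies whole within these numbers, whose meaning the labels do not give. Between exposures inside the stretch, live Bacillus and its supernatant with antibiotics differed in 112 genes, and Bacillus supernatant with and without antibiotics in 127. Both comparisons used the same 4 libraries of Bacillus supernatant with antibiotics, numbered 107 to 110. On the second component these scored 6.40 to 11.2, near live Pseudoalteromonas without antibiotics at 7.22 to 14.1. Live Bacillus with antibiotics scored -13.8 to -8.11 and Bacillus supernatant without antibiotics -8.86 to -1.29. These differences therefore cannot be told apart from the order of numbers inside the stretch.

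Other splits of the same libraries were counted for every comparison. In 26 of the 31 comparisons of 2 groups only the real split gave as many genes, 1 of 35, the smallest share that 8 libraries allow. About 0.886 of the 31 would stand alone by chance. Many of the 31 share a control and are not independent, and no joint test of them was made. Chance is not excluded for each of the 26 taken singly. Weak ones among them were LPS at 5 ng/mL without antibiotics (16 genes, highest other 1, but 0 with only the 2 groups fitted and 1 without LPS replicate 1) and Vibrio supernatant with against without antibiotics (12 genes, highest other 5). In 4 of the 26 a group numbered 99 to 114 was set against a control outside that stretch, so the real split there is also that of the stretch. Over all 26, the highest of the other splits lay between 0 and 906 genes. The latter was for Bacillus supernatant without antibiotics, where the real split gave 2584. The nearest approach was Bacillus supernatant with against without antibiotics, with 86 against 127. That count was 57 without replicate 4 with antibiotics and 27 with only the 2 groups fitted. In 6 comparisons over more groups the real split stood alone, 1 of 100. A share of 1 of 100 is the smallest that 100 splits allow. About 0.14 of the 14 comparisons over more groups would stand alone by chance, and no joint test of them was made. For live against supernatant with antibiotics, with 699 genes and a highest other of 170, the splits argue against chance without excluding it. In the remaining 5 of the 6 the splits mix libraries inside and outside the stretch 99 to 114 and are not read as excluding chance. Their real and highest other counts were 1089 and 341 for antibiotics over 8 exposures, 2626 and 2358 for species as live cells, 5493 and 2016 for species as supernatant, 3220 and 2167 for the interaction over all exposures and 2152 and 2019 for the live Bacillus interaction. The remaining comparisons stand under the other observations.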

How the results depend on the processing

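Leaving out the libraries numbered 99 to 114 was chosen after seeing the data, and so were the 18 added comparisons; all other alternatives were fixed beforehand. RLE size factors left all 27 planned counts within 1.5 times. By the criterion set beforehand, every pair over 0.1, the replicate numbers did not pair the libraries. Deviations from the group mean correlated at 0.0039 between libraries of the same number and -0.0011 otherwise, and 0 of 31 comparisons of 2 groups had every pair over 0.1. In 0 of them did every library correlate best with its own number. The nearest was the LPS dose without antibiotics, at 0.302, 0.171, 0.350 and 0.055, where 3 of 4 libraries correlated best with their own number, and the block called 1 gene, as did the fit without it. With the replicate number as a block, removed against untreated gave 39 genes instead of 37, and no planned count moved by over 1.5 times. The camera tests of gene lists, with either correlation, were not run because no identifier matched a gene name.

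With DESeq2, counts moved to 98 for removed against untreated, 167 for live Bacillus and 78 for LPS at 5 ng/mL without antibiotics, and 2 for the LPS dose without antibiotics. With no filter they moved to 83, 100, 25 and 14 in that order, to 3 for live Vibrio without antibiotics, 165 for LPS at 5 ng/mL with antibiotics and 2 for the LPS dose with antibiotics. With only the groups compared in the fit, which leaves fewer libraries to estimate the spread and runs the filter again, they moved to 118 for removed against untreated, 376 for removed against maintained and 469 for live Vibrio with antibiotics. They fell to 15 for live Bacillus, 1316 for live Pseudoalteromonas, 1613 for Bacillus supernatant, 0 for LPS at 5 ng/mL and 0 for the LPS dose, all without antibiotics, and to 1492 for Bacillus supernatant with antibiotics. Of 9164 genes, the filter then left 2954 for live Pseudoalteromonas and 3468 and 3406 for Bacillus supernatant without and with antibiotics, so fewer genes were tested as well. Against the group kept on antibiotics, counts rose to 614 for live Vibrio, 712 for live Pseudoalteromonas, 439 for Vibrio supernatant, 507 for LPS at 5 ng/mL and 962 for LPS at 5 µg/mL. Without the libraries numbered 99 to 114, they were 57 for removed against untreated, 118 for live Bacillus and 31 for LPS at 5 ng/mL without antibiotics, 165 for the latter with antibiotics and 2 for the LPS dose. Comparisons over several groups then held fewer groups and were not the same tests. Live against supernatant gave 464 without antibiotics, for Vibrio alone, and 1255 with antibiotics, over Vibrio and Pseudoalteromonas. The interaction gave 238, and species 372 for live cells and 1855 for supernatant. The cause was not tested except where stated.

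Leaving out 1 library at a time mostly lowered the counts. The ranges were 253 to 491 for maintained against untreated, 13 to 38 for removed against untreated and 110 to 176 for removed against maintained. Without antibiotics they were 6 to 70 for live Bacillus, 1423 to 2176 for live Pseudoalteromonas, 186 to 309 for Vibrio supernatant, 1 to 18 and 76 to 190 for the LPS doses, and 0 to 8 between the doses. With antibiotics they were 102 to 225 for live Vibrio, 111 to 248 for live Pseudoalteromonas, 155 to 207 for Vibrio supernatant, and 53 to 163 and 163 to 385 for the LPS doses. Leaving out 1 replicate number throughout gave 76 to 93 and 365 to 528 for live against supernatant without and with antibiotics, 608 to 1178 for antibiotics over 8 exposures, 2113 to 2573 for the interaction and 1217 to 2143 for species as live cells. Leaving out untreated replicates 2, 3 and 4 each lowered maintained against untreated (319, 280 and 253), Vibrio supernatant (205, 222 and 190) and LPS at 5 µg/mL (1.58 times for replicate 2, and to 94 and 103 for replicates 3 and 4) by over 1.5 times. Leaving out antibiotics-removed replicates 1, 2 and 3 each did so for live Vibrio (102, 137 and 142), live Pseudoalteromonas (111, 149 and 182) and LPS at 5 µg/mL (171, 237 and 239). Named identifiers were followed through the alternatives, which gave 1115 values, 1 per identifier, comparison and setting. None changed direction, and 65 fell short of the threshold, 54 with 1 library left out. Values without an adjusted p were not counted. The identifiers had been chosen by the smallest p in these same data, so a kept direction was likely beforehand. In simulated counts for live Vibrio against no treatment, at the depths of these libraries and 4 libraries per group, 31% of genes changed 2-fold were recovered; how much of this came from depth was not tested.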

Other observations

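The tests of library composition, for Pseudoalteromonas supernatant and for live Vibrio, were chosen after the result was seen.

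The response to Pseudoalteromonas supernatant was shared with and without antibiotics, with 510 genes higher and 220 lower in each. From the libraries numbered 99 to 114, live Bacillus with antibiotics and live Pseudoalteromonas without were set against it. A composition like theirs is argued against, since fold changes correlated across genes at -0.072 and 0.080. Bacillus supernatant was not compared. A lower mean depth does not apply, as the Pseudoalteromonas supernatant groups averaged 613697 and 674007 counts against 452617 and 427237 in their controls. They were thus deeper on average, and whether that difference in depth played a part was not tested. An effect of the supernatant stays open, and no other technical explanation was tested.

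Live Vibrio libraries with and without antibiotics differed in 1128 genes, while the interaction called 10, or 81 with DESeq2, 91 with no filter, 73 with only the groups compared and 0 to 15 with 1 library left out. A difference in depth is argued against, because 56.5% of the called genes stayed called on average over 8 thinnings of the 8 libraries to 298546 counts. Of the 1128 genes, 85.0% had the sign opposite to a mean fold change taken from libraries numbered 99 to 114. That mean held live Pseudoalteromonas without antibiotics and live Bacillus with antibiotics, each against its control, and left out Bacillus supernatant. The share over all genes was not computed. A difference in library composition along that mean is a candidate explanation, and an effect of antibiotics stays open beside it.

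In 5 comparisons of 2 groups other splits of the 8 libraries matched the real count. Those with 0 genes, live Vibrio against no treatment and the LPS dose with antibiotics, were matched by all 35 splits, as any count matches 0, which says nothing of chance; the other splits gave at most 1 and 0 genes. The LPS dose without antibiotics was matched in 4 of 35 (1 gene, highest other 64), Pseudoalteromonas supernatant with against without antibiotics in 2 of 35 (19 genes, highest other 34) and LPS at 5 ng/mL with against without antibiotics in 3 of 35 (12 genes, highest other 19), so chance is not excluded for these. Live against supernatant without antibiotics was matched in 12 of 100 splits, with up to 2702 genes against 117, which points to a structure of the samples, as 2 of its 6 groups held libraries numbered 99 to 114.

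Among single interactions, LPS at 5 ng/mL had 0 genes, so that all 100 splits matched it and say nothing of chance (highest other 13). Of 100 splits each, 10 matched Pseudoalteromonas supernatant (2 genes, highest other 25), 8 matched Vibrio supernatant (1 gene, highest other 58), 7 matched live Vibrio (10 genes, highest other 964) and 5 matched LPS at 5 µg/mL (3 genes, highest other 86). Chance is not excluded for these. The libraries of an exposure and the controls were shuffled separately. A split can thus keep live Vibrio with and without antibiotics apart while mixing the controls. It then counts largely their direct difference, which called 1128 genes, so the live Vibrio splits cannot decide on chance. For Bacillus supernatant and live Pseudoalteromonas 3 of 100 splits matched (36 and 1526 genes, highest others 136 and 2388), but as other splits called more genes than the real one and mix groups that differ in other ways, chance is not excluded by them.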
